A study of Trachinotus blochii and Siganus canaliculatus with 16 samples.

How the data were processed

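Gill RNA of S. oramin and T. blochii was sequenced at 0, 12 and 72 h of a challenge with C. irritans, per the labels' protocols from polyA RNA prepared with a TruSeq kit and read on an Illumina HiSeq 2500 as paired ends. Fish were 4 months old per the labels, were anaesthetized with MS-222 and were killed at sampling, so replicate numbers at different times name different fish. The labels' protocol gives 3 fish per species and time, and 16 libraries were analysed here, with 2 of S. oramin at 0 h and 2 at 72 h. The same protocol text also speaks of liver and brain and of more libraries than these, while the tissue field of every sample reads gill.

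The deposited tables hold a normalized expression signal per gene and library, per the file headers without the name of the unit. The protocol in the labels mentions read trimming and assembly with Trinity, and the aligner, counter, genome build and normalization of the signal are not given in the sources used here. Values have few decimals in S. oramin, and in T. blochii low values showed no steps of whole reads (0 near-equal neighbours among 476 and 468 low genes, against 0.208 and 0.221 by chance), so counts were not recovered and depth is unknown. Ratios between 2 libraries that differed by less than a relative 1e-06 counted as near-equal. Library totals of the signal are those in the report, and the 10 largest genes held 5.96% to 10.59% of them in S. oramin (10.59% in 0 h replicate 1) and 12.35% to 15.15% in T. blochii. The tables list genes above 1 in every library, with the exception of S. oramin 72 h replicate 2, in which 105 genes are listed at 0 and 329 lie below 1. Of the 105, 64 had a mean of at least 5 in the other libraries, the highest a keratin (Sig_T015643, 1672.4), so a value of 0 may be a failed estimate, and none of these genes is named with a mean. Genes induced from or reduced to silence are mostly missing from the tables.

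Annotation text came from the deposited tables, where 15564 of 15681 tested S. oramin genes (99.3%) carried a description and 4812 of 7604 T. blochii genes (63.3%) a KEGG annotation. T. blochii identifiers carry the name Trachinotus_ovatus as deposited. S. oramin tables had 16026 identifiers, of which 345 in 276 sets were removed because their values equalled those of a kept one in every library. S. oramin identifiers may be transcripts, several identifiers share a description, and reads of close paralogs cannot be told apart, so single members of such families are uncertain. Of 2333 names shared by the species, 1112 were held by exactly 1 gene in each and were matched. No column without a sample was used, and 3 T. blochii annotation summaries were not used here.

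A count model had been planned for counts, with limma-trend on log2(value + 1) as the planned substitute for a normalized unit. The values being normalized, limma 3.58.1 in R 4.3.3 was used, with a pseudocount of 1, no further scaling and no filter on low values. The pseudocount understates fold changes of low genes. The 3 groups of a species shared 1 fit and 1 estimate of the spread, and the species were compared with an interaction in a fit of 6 groups over the matched genes. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05, over all genes tested and, for gene lists, over the list alone. Adjustment over a list alone does not correct for the number of lists or of comparisons. Gene-level p-values rest on 2 or 3 fish per group. They weigh a difference against a spread between fish that is pooled over all groups of a fit and moderated toward a trend over all genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. On simulated values with known fold changes of log2 1, 2 and 3, limma recovered 3.6%, 59% and 79.1% in S. oramin at 12 h, 1.4%, 47.7% and 71.4% at 72 h, and 1.6%, 51.9% and 78.3% for 72 h against 12 h (15681 genes). In T. blochii it recovered 54.1%, 98.7% and 100% at 12 h, 67.3%, 97.1% and 100% at 72 h, and 56.2%, 95.1% and 98.7% for 72 h against 12 h (7604 genes). For the interaction it recovered 49.3%, 95% and 97% at 12 h, and 41.4%, 91.8% and 94.2% at 72 h (1112 genes). Each simulation changed many genes at once, as 55, 78 and 67 at the 3 steps in S. oramin at 12 h. Its noise was normal and drawn independently for each gene. With fewer genes truly changed the adjusted test would recover a smaller share, so these rates may overstate the sensitivity on the real values.

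Gene lists of at least 5 tested genes were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry, and KEGG pathways of 10 to 300 genes were tested with camera in T. blochii (118 pathways). The 30 lists, written as patterns on annotation text, were proinflammatory cytokines and their receptors, chemokines and their receptors, Toll-like receptors and NF-kB signalling, complement, antimicrobial effectors, acute phase proteins, interferon response, MHC and antigen presentation, B cells, T and NK cells, neutrophils and other myeloid cells, ionocytes, epithelium with mucus and junctions, erythrocytes, skeletal muscle, endothelium, extracellular matrix, oxidative phosphorylation, glycolysis, the citrate cycle, fatty acid metabolism, cholesterol synthesis, arginine, tryptophan and polyamine metabolism, the cell cycle, apoptosis, heat shock, hypoxia, oxidative stress, immediate early and handling stress genes, and cytosolic ribosomal proteins. The groups, comparisons, tests, list themes, their 225 patterns, the first set of alternatives and the rule for named genes were fixed before the data were examined. Of the patterns 48 were corrected from the annotation text after a principal component view of the libraries had been seen, but before any gene or list was tested. A list score is the median over a list's genes of log2 values centred on each gene's mean over the libraries of its species.

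The rule for named genes took, per comparison with 0 h, up to 8 largest rises and 8 largest falls among called genes with a mean of at least 5, no overlap between groups and an informative description, up to 3 called genes of each list, 4 and 4 for 72 h against 12 h, 6 and 6 differences between species, and L-amino-acid oxidase genes in every case. It yielded few genes, and the list members named in the report as examples were chosen after their values were seen. Alternatives were median-of-ratios size factors, only the 2 groups compared, a fold threshold of log2 1, the replicate number as a block, summed names, leaving out each library, and, chosen after seeing the data, a pseudocount of 0.1, a mean of at least 5, quantile normalization, array weights, a robust variance prior, identical identifiers kept, and genes listed at 0 left out.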

Results

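Gill transcripts of 2 marine fishes were measured during a challenge with Cryptocaryon irritans, a ciliate that burrows into the skin and gills of marine fish. The fishes were the rabbitfish named Siganus oramin in the sample titles and sources, for which the organism field gives Siganus canaliculatus, and the pompano Trachinotus blochii. The challenge water held 600 theronts, the free-swimming infective stage, per litre, or 6000 for each fish. S. oramin had 2 libraries at 0 h, 3 at 12 h and 2 at 72 h, and T. blochii had 3 at each time. The deposited values were a normalized expression signal and not counts, so the read depth behind each value is unknown. The values summed to between 556321.9 and 609737.1 per library in S. oramin and between 412391.4 and 468172.6 in T. blochii. After removal of duplicated identifiers 15681 genes were tested in S. oramin, and 7604 in T. blochii. Libraries did not group cleanly by time. On log2 values across genes, the S. oramin 0 h libraries had a Pearson correlation of 0.848 with each other. There 0 h replicate 2 had 0.895 to 0.916 with the 12 h libraries, so every S. oramin comparison with 0 h rests on 2 unlike libraries. In T. blochii the highest correlation was between 0 h replicate 1 and 12 h replicate 2 (0.9768). Nearly all listed genes were above 1 in every library, so a gene silent at any time is mostly outside the tables. No fish kept for 12 h or 72 h without the parasite was analysed here, and a difference between times therefore joins infection with time and handling. Mean values are followed by the SD and n, and log2 fold changes were taken on the log2(value + 1) scale.

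The series title relates immunity and metabolism to resistance against the parasite, and the first comparison asked what differed in the gill of S. oramin at 12 h. An eosinophil peroxidase-like gene (Sig_T026861), whose product is a granule enzyme of eosinophils, rose from 3.72 ± 1.0 at 0 h (SD, n = 2) to 221 ± 86.4 at 12 h (SD, n = 3). The other copies with that description had log2 fold changes from −0.97 (Sig_T007050) to 1.91 (Sig_T007051), and none was called over all genes. Reads of close copies cannot be told apart, so the change of this single copy is uncertain. Of 30 chemokine genes, whose products draw leukocytes into tissue, 5 rose and 1 fell with limma, adjusted over the list alone, while over the whole list 15 lay above 0 and 15 below. The chemokine score was −0.46 in 0 h replicate 1 and 0.35 in 0 h replicate 2, against −0.01 ± 0.25 at 12 h (SD, n = 3), and without replicate 1 the number that rose was 0. C-C motif chemokine 19 (Sig_T025452) went from 30.3 ± 27.9 to 334 ± 216, a log2 fold change of 3.58 (SE 0.88, list-alone adjusted p = 0.0318), and a C-C motif chemokine 20-like gene (Sig_T025451) from 204 ± 211 to 1130 ± 400. In the complement list, whose proteins tag and lyse microbes, 4 of 12 genes rose adjusted over the list alone. Among them a complement factor H-like gene (Sig_T029645) went from 13.2 ± 3.2 to 67.2 ± 10.1, a log2 fold change of 2.27 (SE 0.27, list-alone adjusted p = 0.000589).

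Over all 15681 genes, limma called 1 gene higher at 12 h in S. oramin, the eosinophil peroxidase-like gene (log2 fold change 5.50, SE 0.37, adjusted p = 0.015), and 0 lower. At an unadjusted p under 0.05 there were 1693 genes, 700 higher and 993 lower (905 and 824 after size factors), where 784 would be expected with no effect. Here and below such an expected number is a mean, and correlated genes can carry a count far from it with no effect. The call was lost without 0 h replicate 1 (log2 fold change 5.72, adjusted p = 0.26), 0 h replicate 2 (5.28, 0.0997) or 12 h replicate 2 (5.56, 0.133) and with only the 2 groups fitted (5.50, 0.0507), and the count was 2 without 12 h replicate 3. Over all alternatives its adjusted p ran from 0.0101 to 0.26. Adjusted over the list alone, 1 chemokine gene rose without 12 h replicate 2 or 3, and 2 complement genes rose without 0 h replicate 1 or 12 h replicate 3.

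Other single genes passed with adjustment over the list alone at 12 h in S. oramin. That adjustment, here and below, does not correct for the number of lists or comparisons, so some genes may pass it by chance. A tapasin precursor, part of the peptide-loading complex of MHC class I, rose from 2.07 ± 0.891 to 30.7 ± 16.6, while an MHC class Ia gene (Sig_T018965) fell from 186 ± 115 to 7.35 ± 5.47 (both list-alone adjusted p = 0.0147). They were 2 of the 60 genes of the MHC list, of which 0 passed over all genes. The early growth response gene EGR1, an immediate early transcription factor, fell from 349 ± 122 to 72.1 ± 30.5 (log2 fold change −2.29, list-alone adjusted p = 0.0204). A DNA damage-inducible transcript 4-like gene of the hypoxia list rose from 2.17 ± 0.997 to 26.5 ± 14.9 (list-alone adjusted p = 0.00755), and a low-density lipoprotein receptor-like gene of the cholesterol list from 1.96 ± 0.643 to 6.51 ± 1.98 (0.0436). These were the only genes past that test in the immediate early, hypoxia and cholesterol lists, and without 0 h replicate 1 none of the 3 lists had any. The cholesterol and immediate early lists also had 0 without 12 h replicate 1 or 2, and the MHC list had 2 rising and 0 falling without 0 h replicate 2 and 3 falling without 0 h replicate 1.

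As whole lists tested with camera at a preset correlation, 14 of 30 passed at 12 h in S. oramin. Complement was higher, with 12 of 12 genes above 0 and a median log2 fold change of 0.90 (adjusted p = 6.88e-07, and adjusted p = 0.213 with an estimated correlation). The cell cycle list, genes of DNA replication and mitosis, had 45 of 49 genes above 0 and a median of 0.42 (adjusted p = 3.8e-12, and adjusted p = 0.447 with an estimated correlation). For each of the other lists that passed the adjusted p was 0.645 with an estimated correlation. Oxidative phosphorylation, the mitochondrial respiratory chain, had 74 of 91 genes above 0 and a median of 0.48 (adjusted p = 5.99e-09). In the list of neutrophils and other myeloid cells 34 of 40 were above 0, with a median of 0.73 (adjusted p = 1.89e-08), its score being −0.96 in 0 h replicate 1 and 0.22 in 0 h replicate 2. The citrate cycle list had a median of 0.35 (adjusted p = 0.0033), oxidative stress 0.21 (0.00101), interferon response 0.31 (0.00146), ionocytes 0.29 (0.00237), apoptosis 0.42 (0.00538), endothelium 0.37 (0.0148), cholesterol synthesis 0.34 (0.0245), heat shock 0.17 (0.0311) and antimicrobial effectors 0.40 (0.0368). After quantile normalization the median was 0.28 for oxidative phosphorylation, 0.09 for oxidative stress and 0.23 for apoptosis. The skeletal muscle list was lower, at −0.47 (adjusted p = 0.0149), and the erythrocyte list had a median of −0.81 (adjusted p = 0.0523). The mean erythrocyte score was 0.89 ± 0.74 at 0 h (SD, n = 2), with 1.42 in replicate 1 and 0.37 in replicate 2, against −0.03 ± 0.48 at 12 h (SD, n = 3). Without 0 h replicate 1 the adjusted p was 0.352 for antimicrobial effectors and 0.686 for endothelium, both with the opposite sign, 0.724 for interferon response, 0.864 for ionocytes, 0.273 for muscle, 0.294 for apoptosis and 0.2 for heat shock. Cholesterol synthesis was lost without 0 h replicate 2 (0.238), 12 h replicate 1 (0.263) or 12 h replicate 2 (0.0525), the citrate cycle without 12 h replicate 1 (0.058) and heat shock without it (0.0768). Antimicrobial effectors (0.0525) and muscle (0.287) were lost without 12 h replicate 2, and antimicrobial effectors (0.256) and endothelium (0.0625) without 12 h replicate 3. Antimicrobial effectors were also lost with size factors (0.061), quantile normalization (0.0788) or a mean of at least 5 (0.098), heat shock with the latter 2 settings (0.0788 and 0.161) and endothelium with a mean of at least 5 (0.0523). Median, mean and test differed in sign for proinflammatory cytokines (−0.04, 0.25, higher), chemokines (−0.02, 0.45, higher) and Toll-like receptors (−0.16, −0.06, higher), with adjusted p of 0.495, 0.206 and 0.963.

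The comparison of 72 h with 0 h asked what differed in S. oramin at the end of the challenge. Genes of cell division were higher, 33 of 49 rising with limma adjusted over the list alone and 0 falling. Polo-like kinase 1, a mitotic kinase, rose from 11 ± 0.983 at 0 h (SD, n = 2) to 37.7 ± 0.785 at 72 h (SD, n = 2), cyclin-B1 from 10.4 ± 3.97 to 38.4 ± 4.61, and the replication clamp PCNA from 63.9 ± 0.304 to 122 ± 4.13, log2 fold changes of 1.69, 1.83 and 0.92. Of 91 genes of oxidative phosphorylation 54 rose adjusted over the list alone, among them an ATP synthase subunit alpha gene (Sig_T027260), from 142 ± 36.2 to 476 ± 38.4 (log2 fold change 1.76, list-alone adjusted p = 0.0283). Of 42 immediate early and handling stress genes, switched on within minutes of a stimulus, 21 fell and 1 rose adjusted over the list alone. EGR1 fell from 349 ± 122 to 71.7 ± 1.77 (list-alone adjusted p = 0.00641) and an IER2-like gene from 512 ± 39.1 to 137 ± 23.4 (0.00306), and the gene that rose was a copy annotated as Krueppel-like factor 4 (So_GLEAN_10022468, log2 fold change 1.73). The proinflammatory cytokine interleukin-17A/F fell from 38.5 ± 22.8 to 2.13 ± 0.962 (log2 fold change −3.56, list-alone adjusted p = 0.00386).

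Immune and barrier genes moved in both directions at 72 h in S. oramin. Of 12 complement genes 6 rose adjusted over the list alone, including complement C1s, a protease of the classical pathway, from 4.13 ± 0.552 to 32.2 ± 14.4 (log2 fold change 2.63, list-alone adjusted p = 0.00479). Of 30 chemokine genes 6 rose and 3 fell, with the chemokine CK3 going from 11.5 ± 1.93 to 310 ± 5.26 (log2 fold change 4.64, list-alone adjusted p = 0.00873). The acute phase protein serum amyloid P went from 27.6 ± 11.3 to 170 ± 20.9 (log2 fold change 2.63, list-alone adjusted p = 0.000652), and in its list of 8 genes 3 rose and 1 fell. The proteasome subunit PSMB8, which cuts peptides for MHC class I, went from 17.9 ± 7.6 to 201 ± 14.2, and 2 of 60 MHC genes rose (list-alone adjusted p = 0.0324). In the myeloid list 6 of 40 rose, among them macrophage mannose receptor 1, from 2.1 ± 1.12 to 14.8 ± 0.0566, and neutrophil cytosol factor 2, a subunit of the phagocyte oxidase, from 7.41 ± 0.523 to 37.8 ± 12.5. Keratins were the 4 of 121 epithelial genes that rose, with a keratin 8-like gene at 766 ± 22.2 and then 3170 ± 193. The aquaporin-1-like water channel was the 1 ionocyte gene of 61 past the test, falling from 94.2 ± 49.2 to 12.5 ± 2.9 (list-alone adjusted p = 0.0462). Of 47 citrate cycle genes 13 rose, and glycolysis split, with glyceraldehyde-3-phosphate dehydrogenase falling from 343 ± 76.0 to 82.4 ± 20.3 and 3 other genes of 47 rising. In the list of oxidative stress 4 of 76 rose, including a glutathione S-transferase from 49.3 ± 22.1 to 343 ± 115, and the apoptosis regulator BAX went from 23.6 ± 13.5 to 114 ± 9.41 as the 1 of 37 genes of its list (list-alone adjusted p = 0.0443).

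Markers of blood and muscle fell over the same interval in S. oramin. Hemoglobin alpha (LA-Hbalpha1) fell by 2.63 on the log2 scale (list-alone adjusted p = 0.000749), and 4 of 8 erythrocyte genes fell, 3 of them hemoglobins, while carbonic anhydrase 1, also used by ionocytes, rose from 219 ± 153 to 797 ± 32.6. Of 31 skeletal muscle genes 6 fell, including the calcium pump SERCA1 from 15.4 ± 4.37 to 3.42 ± 1.48. The mean score of the erythrocyte list was 0.89 ± 0.74 at 0 h and −0.58 ± 0.17 at 72 h, and that of muscle 0.43 ± 0.3 and −0.29 ± 0.02 (SD, n = 2 each), so between these means both moved with the immediate early list (0.31 ± 0.31 and −0.61 ± 0.15) and opposite to the cell cycle list (−0.52 ± 0.13 and 0.50 ± 0.1). Within 0 h, replicate 1 had the higher erythrocyte and muscle scores but the lower immediate early score (0.09, against 0.53 in replicate 2).

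Over all 15681 genes limma called 0 higher and 0 lower at 72 h in S. oramin, the smallest adjusted p being 0.112, and 2831 genes had an unadjusted p under 0.05 (1870 higher, 961 lower; 784 expected), or 1322 higher and 1393 lower after size factors. Without 72 h replicate 1 the test called 11 lower. Adjusted over the list alone, 0 oxidative phosphorylation genes rose without 0 h replicate 1, 72 h replicate 1 or 72 h replicate 2, and 0 cell cycle genes rose without 72 h replicate 1 and 21 without 72 h replicate 2. The immediate early genes that fell were 10 and 12 without 72 h replicates 1 and 2, and chemokine genes numbered 2 rising without 0 h replicate 1, 3 rising and 1 falling without 72 h replicate 1, and 0 without 72 h replicate 2. Of the citrate cycle genes 0 rose without 0 h replicate 1 or 72 h replicate 1 and 4 without 72 h replicate 2, and of the muscle genes 0 fell without 0 h replicate 1 or 72 h replicate 2. In the myeloid list 1 rose without 72 h replicate 1 and 14 rose without 0 h replicate 2, while complement kept between 4 and 6 rising with any library left out. The calls of keratins, aquaporin-1-like, carbonic anhydrase 1, glutathione S-transferase and BAX were lost without 0 h replicate 1, 72 h replicate 1 or 72 h replicate 2, those of glycolysis without any 1 of the 4 libraries, and those of MHC without either 72 h library. Without 0 h replicate 2, 21 ionocyte genes rose and 2 fell and 13 epithelial genes rose and 11 fell. In the acute phase list 1 rose without 0 h replicate 2 or either 72 h library. The median of all genes was shifted by 0.103 on the log2 scale, and by −0.039 after median-of-ratios size factors, so list medians stand against that shift.

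Of the 30 lists 13 passed the camera test at 72 h against 0 h in S. oramin with the preset correlation, and 0 with an estimated one. Oxidative phosphorylation had a median log2 fold change of 1.12, with 85 of 91 genes above 0 (adjusted p = 4.27e-17, and adjusted p = 0.454 with an estimated correlation). The cell cycle list had 0.95 and 47 of 49 (8.69e-16, and adjusted p = 0.303 with an estimated correlation), the citrate cycle 0.97 and 44 of 47 (4.09e-08, and 0.443), and complement 1.5 and 11 of 12 (4.71e-05, and 0.303). Immediate early genes had −0.89 and 34 of 42 below 0 (adjusted p = 5.06e-11, and adjusted p = 0.319 with an estimated correlation). Skeletal muscle had −0.71 (1.18e-07), extracellular matrix −0.24 (0.000876), erythrocytes −1.21 (0.00273), Toll-like receptors −0.35 (0.00729) and proinflammatory cytokines −0.33 (0.0222), each with an adjusted p = 0.443 with an estimated correlation. Ionocytes had 0.49 (0.0206) and oxidative stress 0.39 (0.0333), both with an adjusted p = 0.841 with an estimated correlation. Cytosolic ribosomal proteins had −0.12 (adjusted p = 0.00729, and adjusted p = 0.909 with an estimated correlation) but 0.09 after quantile normalization (adjusted p = 0.305). After size factors the median was −0.29 for ribosomal proteins, −0.37 for extracellular matrix and 0.24 for oxidative stress. Ionocytes (adjusted p = 0.439), oxidative stress (0.267) and ribosomal proteins (0.519, opposite sign) were lost without 0 h replicate 1, and proinflammatory cytokines (0.263) and Toll-like receptors (0.203) without 0 h replicate 2. Without 72 h replicate 1 the adjusted p was 0.115 for proinflammatory cytokines, 0.0722 for Toll-like receptors and 0.0845 for oxidative stress, and without 72 h replicate 2 it was 0.0945 for ribosomal proteins. Median, mean and test differed in sign for glycolysis (0.14, −0.03, lower; adjusted p = 0.56), and median and mean for hypoxia (−0.09, 0.02; adjusted p = 0.636).

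**Figure D1:**
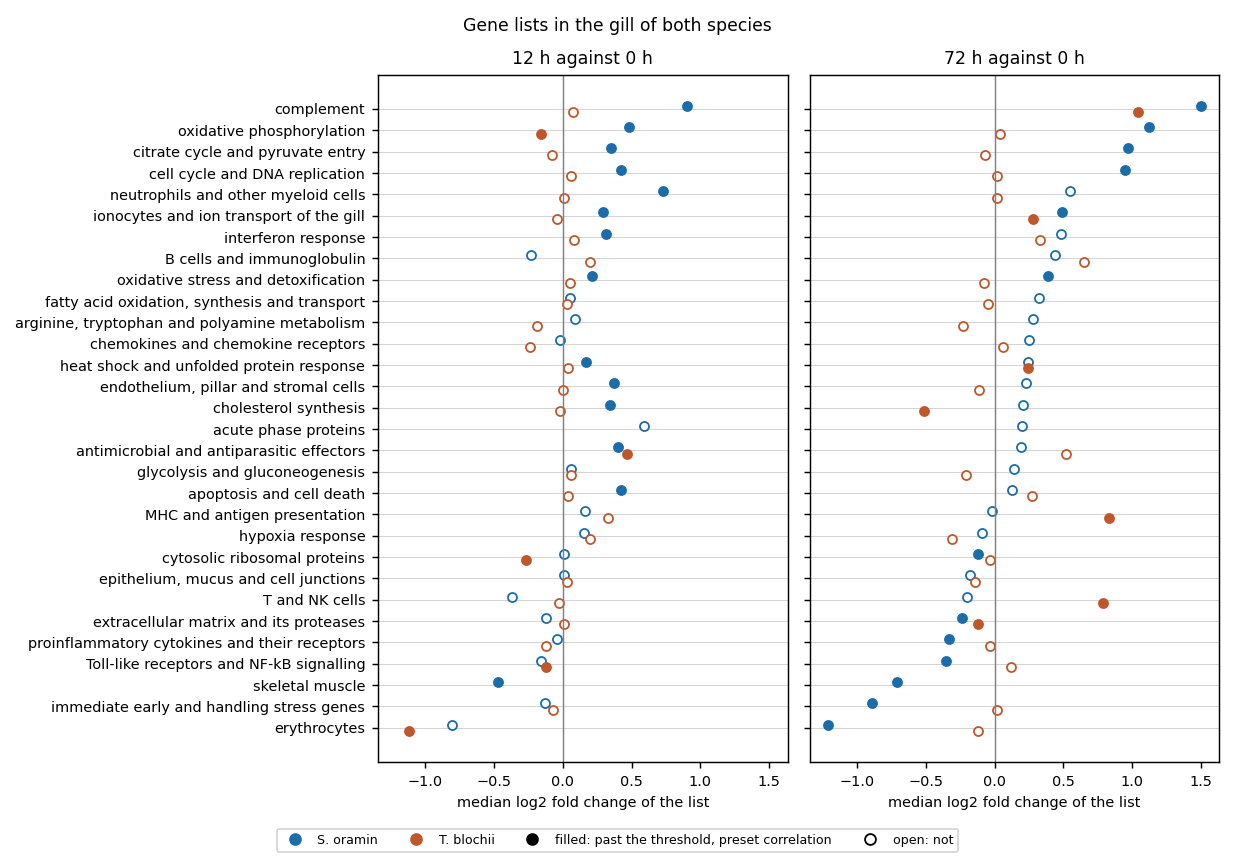
Median log2 fold change of each gene list at 12 h against 0 h (left) and 72 h against 0 h (right), S. oramin in blue and T. blochii in orange; filled points passed the camera test with the preset correlation. In S. oramin at 72 h oxidative phosphorylation lies at 1.12 and immediate early genes at −0.89.

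**Figure D2:**
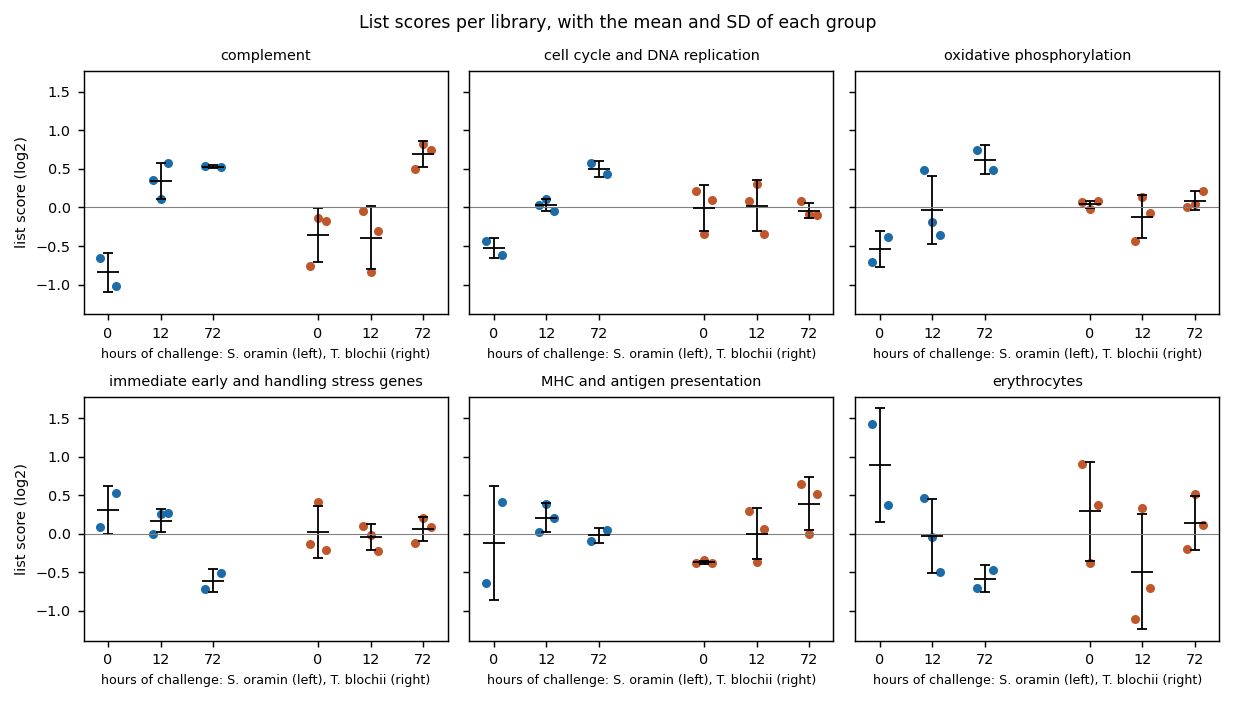
Score of 6 gene lists in each library, the median log2 value of the list's genes after centring each gene, with a dash for the group mean and bars for the SD; S. oramin is in blue on the left of each panel and T. blochii in orange on the right, by hours of challenge. The cell cycle score of S. oramin goes from −0.52 at 0 h to 0.50 at 72 h.

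The comparison of 72 h with 12 h in S. oramin asked what differed between the later stages. The eosinophil peroxidase-like gene Sig_T026861 fell from 221 ± 86.4 at 12 h (SD, n = 3) to 3.67 ± 0.99 at 72 h (SD, n = 2). Proinflammatory genes fell with it when adjusted over the list alone: interleukin-17A/F went from 33.2 ± 12.2 to 2.13 ± 0.962 (log2 fold change −3.41, list-alone adjusted p = 0.00284), interleukin-1 beta from 188 ± 160 to 24.8 ± 3.39, and the prostaglandin synthase PTGS2 from 490 ± 71.3 to 105 ± 16.2. They were the 3 of 16 genes of that list past the test, and 3 of 20 genes of Toll-like receptors and NF-kB signalling fell too, including TLR22 from 21.8 ± 14.8 to 2.52 ± 1.64. In the MHC list PSMB8 rose, from 4.87 ± 3.78 to 201 ± 14.2 (log2 fold change 5.32, list-alone adjusted p = 0.00134), the 1 gene of 60 past the test.

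In the myeloid list 13 of 40 genes passed adjusted over the list alone, 6 rising and 7 falling. Copies annotated alike as eosinophil peroxidase-like moved apart, Sig_T007049 falling from 2350 ± 1200 to 332 ± 41.9 and Sig_T007054 rising from 30.7 ± 44.1 to 175 ± 73.0. Leukocyte cell-derived chemotaxin 2 fell from 144 ± 125 to 13.4 ± 3.15 (list-alone adjusted p = 0.018). Of 42 immediate early genes 18 fell, including an IER2-like gene from 440 ± 13.4 to 137 ± 23.4, and of 47 citrate cycle genes 9 rose. Heme oxygenase, which degrades heme, rose from 5.2 ± 0.362 by a log2 fold change of 2.61, and the DNA damage-inducible transcript 4-like gene fell from 26.5 ± 14.9 to 2.22 ± 0.509 (both list-alone adjusted p = 0.00828). Hemoglobin alpha fell from 2730 ± 348 to 931 ± 178, 1 of 3 erythrocyte genes that did, and SERCA1 fell by 1.77 on the log2 scale as the 1 muscle gene past the test. The ionocyte genes that fell were sodium/potassium ATPase alpha-2 and an aquaporin-3-like gene, with log2 fold changes of −1.67 and −1.57 (list-alone adjusted p = 0.0474).

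Over all genes limma called 0 higher and 1 lower at 72 h against 12 h, Sig_T026861 (log2 fold change −5.52, SE 0.37, adjusted p = 0.0147), and 2207 genes had an unadjusted p under 0.05 (1582 higher, 625 lower; 784 expected). The call was lost without 12 h replicate 2 (log2 fold change −5.57, adjusted p = 0.131) or 72 h replicate 2 (−5.30, 0.159) and with only the 2 groups fitted (−5.52, 0.0818), with a range of 0.00293 to 0.159 over all alternatives. Without 72 h replicate 1 the test called 11 lower, and with array weights, chosen after seeing the data, it called 16 higher and 21 lower. The median of all genes was shifted by 0.185, by −0.005 after size factors and by 0.047 after quantile normalization, and after size factors 673 genes were higher and 1082 lower at an unadjusted p under 0.05. Adjusted over the list alone, 1 proinflammatory gene fell without either 72 h library. The immediate early genes that fell were 7 and 6 without 12 h replicates 2 and 3, and 5 and 9 without 72 h replicates 1 and 2. The citrate cycle genes were 0 without any of those 4 libraries. In the myeloid list 0 rose and 2 fell without 72 h replicate 1, 3 rose and 3 fell without 72 h replicate 2, and 3 rose and 6 fell without 12 h replicate 3. Of the Toll-like receptor genes 1 fell without 72 h replicate 1 and 0 without 72 h replicate 2, and 0 erythrocyte genes fell without either. The muscle gene was lost without any 1 of the 5 libraries, the ionocyte genes without any 1 but 12 h replicate 3 (1 fell), and both hypoxia genes without 72 h replicate 2.

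Camera with the preset correlation called 16 of 30 lists at 72 h against 12 h in S. oramin. Immediate early genes had a median log2 fold change of −0.76 (adjusted p = 4.43e-13), extracellular matrix −0.18 (7.37e-06) and epithelium −0.19 (0.000266), each with an adjusted p = 0.37 with an estimated correlation. Oxidative phosphorylation had 0.63, with 86 of 91 genes above 0 (3.83e-08), MHC −0.17 (0.00347), the myeloid list −0.12 (0.0106) and cholesterol synthesis −0.27 (0.0107), each with an adjusted p = 0.666 with an estimated correlation. The cell cycle list had 0.43 and 47 of 49 above 0 (2.1e-05), muscle −0.39 (3.14e-05), Toll-like receptors −0.19 (0.000508), apoptosis −0.10 (0.0106) and hypoxia −0.10 (0.0107), each with an adjusted p = 0.402 with an estimated correlation. The citrate cycle had 0.61 (7.08e-05, and adjusted p = 0.621 with an estimated correlation), proinflammatory cytokines −0.09 with a mean of −0.66 (0.000508, and 0.4), erythrocytes −0.58 (0.0106, and 0.508) and ribosomal proteins −0.16 (5e-06, and 0.746). After size factors the median was 0.41 for oxidative phosphorylation, 0.26 for the cell cycle, −0.36 for extracellular matrix and epithelium, −0.38 for MHC and ribosomal proteins, −0.29 for myeloid genes and −0.46 for cholesterol synthesis. It was −0.60 for muscle, −0.39 for Toll-like receptors, −0.27 for apoptosis and proinflammatory cytokines, and −0.32 for hypoxia. After quantile normalization the ribosomal median was 0.00 (adjusted p = 0.702), and MHC and myeloid genes were lost (both 0.0582), the latter also with size factors (0.0705). MHC (adjusted p = 0.0904) and myeloid genes (0.0756) were lost without 72 h replicate 1, erythrocytes (0.0908) and cholesterol synthesis (0.368) without 12 h replicate 1, and cholesterol synthesis without 72 h replicate 2 (0.0708) or with a mean of at least 5 (0.0716). The test pointed lower while the median was above 0 for interferon response (0.22), T and NK cells (0.11), glycolysis (0.07), heat shock (0.02) and oxidative stress (0.12, and −0.08 after size factors), none of which passed.

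**Figure D3:**
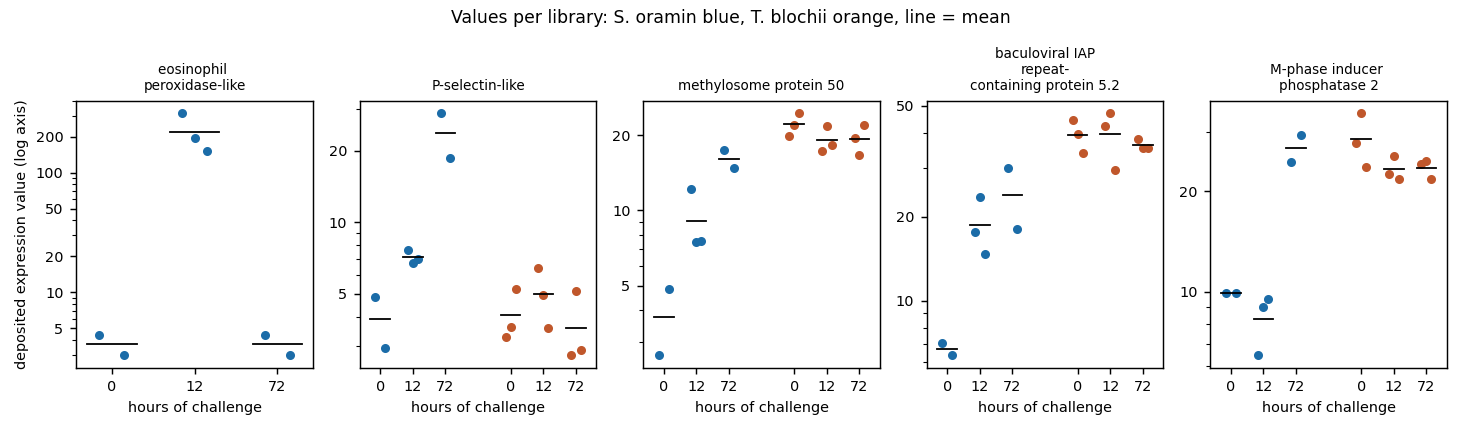
Deposited expression value per library on a log axis, by hours of challenge, for 5 genes, with a line at the group mean; S. oramin is in blue and T. blochii in orange, and the eosinophil peroxidase-like gene is shown for S. oramin alone. That gene has means of 3.72, 221 and 3.67 at 0, 12 and 72 h.

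In T. blochii the comparison of 12 h with 0 h asked what differed early in the challenge. Ribosomal protein genes were lower as a list, 39 of 40 lying below 0 with a median log2 fold change of −0.27 (−0.10 after quantile normalization; adjusted p = 6.02e-08), as were oxidative phosphorylation genes, 43 of 48 lying below 0 with a median of −0.16 (adjusted p = 3.45e-05). Both had an adjusted p = 0.899 with an estimated correlation, and without 12 h replicate 1 oxidative phosphorylation lost its call and changed sign (adjusted p = 0.861). Ribosomal protein L15 had 574 ± 97.6 at 0 h and 425 ± 78.2 at 12 h (SD, n = 3 each; list-alone adjusted p = 0.457), and an NDUFA4-like cytochrome c oxidase subunit 27 ± 0.836 and 16.7 ± 5.64 (0.353). All 5 erythrocyte genes lay below 0, with a median of −1.12 (adjusted p = 0.0015, and adjusted p = 0.391 with an estimated correlation), and all 8 antimicrobial effectors lay above 0, with a median of 0.47 (adjusted p = 0.012). Toll-like receptors had a median of −0.12 (adjusted p = 0.0149), and these and the antimicrobial effectors had an adjusted p = 0.899 with an estimated correlation.

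These were the 5 of 28 lists past the camera test at 12 h in T. blochii. In each of the lists 0 genes passed adjusted over the list alone. The mean erythrocyte score was 0.29 ± 0.64 at 0 h and −0.49 ± 0.75 at 12 h (SD, n = 3 each). Limma called 0 of 7604 genes higher and 0 lower, and 213 had an unadjusted p under 0.05, where 380 would be expected with no effect. The erythrocyte call was lost without 12 h replicate 1 (adjusted p = 0.0547). Antimicrobial effectors were lost without 0 h replicate 1 (0.0939), 12 h replicate 1 (0.532) or 12 h replicate 3 (0.503), and Toll-like receptors without 0 h replicate 2 (0.251) or 12 h replicate 2 (0.0906) and with array weights (0.253), while 13 lists passed without 12 h replicate 2. Median, mean and test differed in sign for T and NK cells (−0.03, 0.00, higher), myeloid cells (0.01, −0.06, lower), epithelium (0.03, −0.05, lower) and extracellular matrix (0.01, −0.04, lower), none of which passed. Among the pathways of the deposited KEGG annotation Ribosome had 60 of 62 genes below 0 (median −0.25, adjusted p = 1.76e-08) and oxidative phosphorylation 49 of 62 (−0.12, 0.0167), both with an adjusted p = 0.998 with an estimated correlation.

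In T. blochii the comparison of 72 h with 0 h asked what differed at the end of the challenge, and immune genes were among those that rose. Interferon regulatory factor 1, a transcription factor of the interferon response, rose from 292 ± 2.91 at 0 h to 714 ± 62.0 at 72 h (SD, n = 3 each; log2 fold change 1.28, SE 0.19, list-alone adjusted p = 0.000437), and IRF8 and the cytokine signalling inhibitor SOCS1 rose with it, the 3 of 10 interferon genes past the test adjusted over the list alone. Of 6 complement genes 3 rose, all subunits of C1q, which starts the classical pathway, with a C1q subunit C gene (Trachinotus_ovatus_newGene_8227) going from 88.0 ± 13.6 to 230 ± 49.9 (log2 fold change 1.37, list-alone adjusted p = 0.00129). Of 5 MHC genes 4 rose, including tapasin from 97.4 ± 3.94 to 178 ± 28.9 (list-alone adjusted p = 0.0146), and of 21 chemokine genes 2 rose, a CXCL10-like gene from 18.6 ± 4.0 to 75.4 ± 15.5 (0.0141) and CCL19 from 181 ± 51.9 to 365 ± 17.8 (0.0196).

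Genes of other lists passed the test at 72 h in T. blochii as well. Of 14 heat shock genes 3 rose, with the chaperone HSP90-alpha going from 19.4 ± 5.11 to 58.0 ± 14.1 (list-alone adjusted p = 0.00364). Of 33 epithelial genes 2 rose and 4 fell, a claudin-10-like junction gene going from 19.1 ± 4.26 to 44.7 ± 17 and a keratin 13-like gene from 9940 ± 1270 to 4640 ± 1830 (both list-alone adjusted p = 0.0211). AGR2, which folds mucins, fell from 613 ± 61.9 to 330 ± 35 (0.015). Laminin gamma 2, of the basement membrane, fell from 21.6 ± 3.74 to 8.52 ± 0.895 as the 1 of 24 matrix genes past the test (0.0107), and a carbonic anhydrase 1-like gene rose from 105 ± 25.5 by a log2 fold change of 1.46 as the 1 of 5 erythrocyte genes (0.014).

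Limma called 0 of 7604 genes higher and 0 lower at 72 h in T. blochii, the smallest adjusted p being 0.143, and 704 had an unadjusted p under 0.05 (408 higher, 296 lower; 380 expected). The test called 4 higher without 72 h replicate 2 and 1 lower without 72 h replicate 1. With only the 2 groups fitted it called 10 higher and 1 lower, and with array weights, chosen after seeing the data, 247 higher and 137 lower. Adjusted over the list alone, between 2 and 4 interferon and complement genes rose with any library left out. The MHC genes were 0 without 72 h replicate 1 or 3, 1 without 0 h replicate 3 and 2 without 0 h replicate 1, and the chemokine genes 0 without 0 h replicate 1 or 72 h replicate 2 and 1 without 0 h replicate 3, 72 h replicate 1 or 72 h replicate 3. Of the epithelial genes 0 rose without 0 h replicates 2 and 3 or 72 h replicates 1 and 3, each left out alone, and 1 rose and 2 fell without 0 h replicate 1. Laminin gamma 2 was lost without 0 h replicate 1, 0 h replicate 2 or 72 h replicate 3, the carbonic anhydrase gene without 0 h replicate 3 or 72 h replicate 3, and 6 heat shock genes rose without 72 h replicate 2. Camera with the preset correlation called 7 of 28 lists. Complement had a median log2 fold change of 1.04 (adjusted p = 9.67e-05), ionocytes 0.28 with 24 of 29 genes above 0 (0.000279), MHC 0.83 (0.000357) and heat shock 0.24 (0.00632), each with an adjusted p = 0.267 with an estimated correlation. T and NK cells had 0.79 with 8 of 8 genes above 0 (0.00207), cholesterol synthesis −0.51 with 9 of 9 below 0 (0.00343) and extracellular matrix −0.12 (0.0107), each with an adjusted p = 0.404 with an estimated correlation. T and NK cells were lost without 72 h replicate 2 (adjusted p = 0.07), extracellular matrix without 0 h replicate 1 (0.0588) or with array weights (0.0786), and heat shock with a mean of at least 5 (0.0832), and 12 lists passed without 72 h replicate 3. The erythrocyte list had a median of −0.12 (0.979), and the cell cycle list a median of 0.02, a mean of −0.01 and a test pointing lower (0.861). The KEGG pathways past the test were biosynthesis of amino acids (median −0.17, adjusted p = 0.0146) and Lysosome (0.14, 0.0268), both with an adjusted p = 0.991 with an estimated correlation.

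From 12 h to 72 h in T. blochii 3 chemokine and 4 complement genes rose adjusted over the list alone, the comparison asking what differed between the later stages. CCL19 went from 117 ± 32.8 to 365 ± 17.8 (SD, n = 3 each; log2 fold change 1.67, list-alone adjusted p = 0.00113), a CCL20-like gene from 476 ± 188 to 1900 ± 283 (2.08, 0.0127) and the CXCL10-like gene from 20.6 ± 11.3 to 75.4 ± 15.5 (1.99, 0.00643), the 3 of 21 chemokine genes past the test. Of 6 complement genes 4 rose, the C1q subunits and complement factor D, the latter from 16.4 ± 1.28 to 33.4 ± 2.62 (list-alone adjusted p = 0.0164). ZAP70, a kinase of the T cell receptor, rose from 13.2 ± 4.42 to 27.8 ± 9.14 (0.0397). Of 33 epithelial genes 4 rose and 6 fell: the claudin-10-like gene went from 10.4 ± 3.1 to 44.7 ± 17, AGR2 from 724 ± 166 to 330 ± 35, and a mucin-2-like gene from 36.3 ± 17.8 to 10.9 ± 8.06 (0.0412). Carbonic anhydrase 1-like, counted in both the ionocyte and the erythrocyte list, rose from 65.1 ± 28.9 by a log2 fold change of 2.20 (0.00423 over the ionocyte list).

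Limma called 0 of 7604 genes higher and 0 lower from 12 h to 72 h in T. blochii, the smallest adjusted p being 0.0929, and 937 had an unadjusted p under 0.05 (517 higher, 420 lower; 380 expected). Without 12 h replicate 3 the test called 6 higher and without 72 h replicate 2 it called 2 higher, while it called 2 lower without 12 h replicate 2, 3 lower without 72 h replicate 1 and 9 higher with array weights. Adjusted over the list alone, 2 chemokine genes rose and 1 fell without 12 h replicate 2, and between 3 and 5 complement genes rose with any library left out. Of the epithelial genes 2 rose and 4 fell without 12 h replicate 1, 2 rose and 3 fell without 12 h replicate 2 or 72 h replicate 3, and 4 rose and 10 fell without 72 h replicate 1. The T cell gene was lost without 12 h replicate 2 or 72 h replicate 2. Camera with the preset correlation called 11 of 28 lists. Oxidative phosphorylation had a median log2 fold change of 0.21 (adjusted p = 0.00197) and chemokines 0.42 (0.0206), each with an adjusted p = 0.546 with an estimated correlation, and ribosomal proteins 0.24 with 40 of 40 genes above 0 (0.00273, and 0.646). Ionocytes had 0.31 (0.20 after quantile normalization; 0.00273), Toll-like receptors 0.43 (0.0101), glycolysis −0.30 (0.0113) and heat shock 0.26 (0.0206), each with an adjusted p = 0.495 with an estimated correlation. Complement had 1.11 (0.0038) and T and NK cells 0.69 (0.00789), each with an adjusted p = 0.504 with an estimated correlation, followed by extracellular matrix at −0.20 (0.0313, and 0.509) and cholesterol synthesis at −0.29 (0.0419, and 0.533). Without 12 h replicate 1 the adjusted p was 0.51 for oxidative phosphorylation, 0.202 for ribosomal proteins, 0.113 for heat shock and 0.0795 for extracellular matrix. Without 12 h replicate 2 it was 0.819 for chemokines, 0.237 for T and NK cells and 0.654 for cholesterol synthesis, and without 12 h replicate 3 it was 0.387 for extracellular matrix and 0.136 for glycolysis. Cholesterol synthesis had 0.151 without 72 h replicate 1. Without 72 h replicate 2 the adjusted p was 0.116 for chemokines, 0.0752 for T and NK cells, 0.117 for cholesterol synthesis and 0.928 for ribosomal proteins, and without 72 h replicate 3 it was 0.124 for extracellular matrix, 0.0873 for oxidative phosphorylation and 0.106 for heat shock. With array weights it was 0.0901 for chemokines and ribosomal proteins and 0.0603 for T and NK cells, and with a mean of at least 5 it was 0.0675 for cholesterol synthesis and 0.113 for heat shock. The KEGG pathway oxidative phosphorylation had 50 of 62 genes above 0 (median 0.21, adjusted p = 0.000946, and adjusted p = 0.995 with an estimated correlation). Myeloid cells had a median of −0.01, a mean of 0.16 and a test pointing higher (0.448).

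Whether the species responded differently was tested with an interaction over 1112 genes matched 1 to 1 by name, and differences are S. oramin minus T. blochii. A shared name does not establish that 2 genes are orthologs. At 72 h 4 differences were above 0 and 1 below, and in each of the 4 the mean was higher at 72 h in S. oramin and slightly lower in T. blochii. P-selectin-like, an adhesion receptor for leukocytes, went from 3.91 ± 1.35 to 23.7 ± 7.24 in S. oramin (SD, n = 2 each) and from 4.06 ± 1.04 to 3.59 ± 1.32 in T. blochii (SD, n = 3 each), a difference of log2 fold changes of 2.49 (SE 0.41, adjusted p = 0.0181). Methylosome protein 50, a partner of an arginine methyltransferase, differed by 2.07 (SE 0.36, 0.0181), with 3.76 ± 1.58 and 16.1 ± 1.87 against 22.1 ± 2.34 and 19.3 ± 2.67. The mitotic genes baculoviral IAP repeat-containing protein 5.2 and M-phase inducer phosphatase 2 differed by 1.77 (SE 0.36, 0.0406) and 1.61 (SE 0.29, 0.0215). The former went from 6.69 ± 0.467 to 24 ± 8.35 and from 39.2 ± 5.28 to 36.1 ± 1.58, the latter from 9.91 ± 0.0354 to 27 ± 3.61 and from 28.6 ± 5.37 to 23.5 ± 1.61. The difference below 0 was the ankyrin repeat and SOCS box protein 5-like gene, at −1.95 (SE 0.4, 0.0406), with 4.02 ± 1.71 and 1.09 ± 0.24 against 2.15 ± 0.866 and 4.1 ± 0.623. At 12 h the 1 gene past the test was acetylserotonin O-methyltransferase-like, named for the last step of melatonin synthesis, at −1.66 (SE 0.26, adjusted p = 0.0143), with 3.42 ± 0.523 and 1.12 ± 0.052 against 1.77 ± 0.32 and 3.19 ± 0.213. The ankyrin repeat gene and acetylserotonin O-methyltransferase-like fall below a mean of 5 in both species, and P-selectin-like does in T. blochii. These genes were chosen after their values were seen. With limma over all genes of a species, none of them passed in its own species. At 72 h their adjusted p ran from 0.127 to 0.169 in S. oramin and from 0.347 to 0.965 in T. blochii. The S. oramin means of 1.09 and 1.12 lie near 1.01, the smallest value listed outside 72 h replicate 2, so the spread there may be understated.

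At an unadjusted p under 0.05 there were 94 matched genes at 12 h, of which 0 passed limma's adjusted test above 0, and 242 at 72 h (191 above 0, 51 below), where 56 would be expected with no effect, or 144 above and 73 below at 72 h after size factors. The median of all matched differences at 72 h was 0.216, and 0.063 after size factors within each species, which left 2 genes above 0 and 0 below (adjusted p = 0.0523 for protein 5.2 and the ankyrin repeat gene, 0.0543 for the phosphatase). After quantile normalization it was 0.089, with 4 above and 0 below (0.0604 for the ankyrin repeat gene). With names summed in each species 29 differences were above 0 and 11 below at 72 h, and with a mean of at least 5 there were 0 below at both times. Array weights ended the calls of acetylserotonin O-methyltransferase-like (0.057), protein 5.2 (0.052) and the ankyrin repeat gene (0.0506). Acetylserotonin O-methyltransferase-like was lost without S. oramin 0 h replicate 1 (adjusted p = 0.162) or 12 h replicate 2 (0.0545) and without T. blochii 0 h replicate 1 (0.0523), 0 h replicate 3 (0.0733), 12 h replicate 1 (0.0512) or 12 h replicate 2 (0.0551). Without S. oramin 72 h replicate 1 the adjusted p was 0.0714 for P-selectin-like, 0.0743 for methylosome protein 50, 0.17 for protein 5.2, 0.0539 for M-phase inducer phosphatase 2 and 0.0779 for the ankyrin repeat gene. Protein 5.2 was also lost without S. oramin 0 h replicate 1 (0.0612), and without T. blochii 0 h replicates 1 (0.12) and 3 (0.0543) and 72 h replicates 1 (0.0684), 2 (0.0819) and 3 (0.11). The phosphatase was lost without S. oramin 72 h replicate 2 (0.0699), T. blochii 0 h replicate 1 (0.0643) and 72 h replicate 3 (0.077). The ankyrin repeat gene was lost without S. oramin 0 h replicate 1 (0.0935) and 72 h replicate 2 (0.0782), and without T. blochii 0 h replicates 1 (0.104) and 3 (0.0522) and 72 h replicates 1 (0.0705), 2 (0.0819) and 3 (0.077). Without S. oramin 0 h replicate 2 the counts were 43 above and 19 below at 72 h, and 15 above and 9 below at 12 h. At 72 h there were 12 above and 3 below without T. blochii 0 h replicate 2, 0 above and 2 below without S. oramin 72 h replicate 1, 3 below without S. oramin 0 h replicate 1, and 2 above and 0 below without T. blochii 0 h replicate 1 or 72 h replicate 3. At 12 h there was 1 above without S. oramin 12 h replicate 3.

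As lists, 2 of the 6 with at least 5 matched genes differed between the species at each time. At 72 h the 9 matched cell cycle genes had differences all above 0, with a median of 1.10 (0.96 in S. oramin, 0.04 in T. blochii; adjusted p = 0.000424), and 8 passed adjusted over the list alone. The 9 oxidative phosphorylation genes had a median of 1.27 (1.36 and 0.13; adjusted p = 0.00394), 5 of them past that test. With an estimated correlation both had an adjusted p = 0.259. At 12 h the medians were 0.77 for oxidative phosphorylation (0.53 and −0.23; adjusted p = 0.0011) and 0.23 for the cell cycle (0.47 and 0.10; adjusted p = 0.0084), 1 gene of each passing adjusted over the list alone and both having an adjusted p = 0.233 with an estimated correlation. The cell cycle call at 12 h was lost without S. oramin 0 h replicate 2 (adjusted p = 0.201), and oxidative phosphorylation at 72 h without S. oramin 72 h replicate 1 (0.0529). Adjusted over the list alone, the cell cycle genes at 72 h were 3 without S. oramin 0 h replicate 2, S. oramin 72 h replicate 1 or T. blochii 0 h replicate 1, and 5 without T. blochii 0 h replicate 3 or 72 h replicate 3. The oxidative phosphorylation genes were 3 without S. oramin 0 h replicate 1 or 72 h replicate 1. At 12 h the cell cycle gene was lost without S. oramin 0 h replicate 2, with 2 passing without T. blochii 0 h replicate 2, and the oxidative phosphorylation gene without S. oramin 0 h replicate 1, T. blochii 0 h replicate 2 or 12 h replicate 1. The mean erythrocyte score, which moved opposite to these lists in S. oramin, was 0.89 ± 0.74 and −0.58 ± 0.17 at 0 h and 72 h there and 0.29 ± 0.64 and 0.14 ± 0.35 in T. blochii. At 72 h oxidative stress had a median difference of 0.62 (adjusted p = 0.124), Toll-like receptors −0.20 (0.0993), ionocytes −0.25 (0.235) and apoptosis 0.45 with a test pointing lower (0.942). At 12 h these were 0.29 (0.175), −0.02 (0.01 after size factors) with a test pointing higher (0.99), 0.74 (0.0658) and 0.58 (0.283).

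L-amino-acid oxidase, an enzyme that releases hydrogen peroxide from amino acids, is known as an antiparasitic protein of S. oramin and its genes were followed whatever their values. In S. oramin gene Sig_T020365 had 25.9 ± 33.3 at 0 h (SD, n = 2), 51.3 ± 18.5 at 12 h (SD, n = 3) and 36.6 ± 14.8 at 72 h (SD, n = 2), and Sig_T020370 had 20.8 ± 27.5, 30.3 ± 17.9 and 27.7 ± 1.12. Their log2 fold changes against 0 h were 1.94 (SE 1.02, adjusted p = 0.52) and 1.51 (0.621) at 12 h, and 1.47 (SE 1.12, 0.517) and 1.54 (0.523) at 72 h. The 0 h libraries had 2.35 and 49.4 for the former gene and 1.35 and 40.2 for the latter, and without 0 h replicate 1 the log2 fold changes were −0.02 and −0.55 at 12 h and −0.48 and −0.52 at 72 h. In T. blochii Trachinotus_ovatus_newGene_3758 had 10.0 ± 6.57, 21.3 ± 19.1 and 23 ± 1.92 at 0, 12 and 72 h (SD, n = 3 each), newGene_3759 had 9.32 ± 3.17, 14.2 ± 11.4 and 29.8 ± 4.82, and newGene_3760 had 8.44 ± 3.05, 11 ± 7.86 and 24.6 ± 8.0. At 72 h against 0 h their log2 fold changes were 1.35 (SE 0.61, adjusted p = 0.539), 1.62 (SE 0.53, 0.347) and 1.45 (SE 0.52, 0.405), so none passed, and with array weights the second and the third passed (adjusted p = 0.0254 and 0.0316). At 12 h they were 0.91, 0.26 and 0.13 (each adjusted p = 0.999).

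The responses at 12 h and 72 h within a species share the 0 h libraries. Across genes, which are not independent replicates, the log2 fold changes at the 2 times had a Pearson correlation of 0.628 in S. oramin and 0.174 in T. blochii, where simulated unchanged groups against the same controls gave 0.545 and 0.5. The covariance was 0.261 in S. oramin against a simulated 0.13, and 0.018 in T. blochii against 0.045. In T. blochii both values thus lay below the simulated ones. The simulation drew genes independently, so it held no deviation of a whole library that many genes share. The controls are too few to split with 2 in each part, so part of the excess in S. oramin may come from the shared 0 h libraries. With 0 genes called at 72 h against 0 h in either species, no gene could be called at both times.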

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

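All tests of explanations in this part were chosen after the results were seen. The test of the difference between the species singled out 6 matched genes. Acetylserotonin O-methyltransferase-like differed by −1.66 (log2, S. oramin minus T. blochii) at 12 h. At 72 h P-selectin-like differed by 2.49, methylosome protein 50 by 2.07, baculoviral IAP repeat-containing protein 5.2 by 1.77, M-phase inducer phosphatase 2 by 1.61 and ankyrin repeat and SOCS box protein 5-like by −1.95. Among lists, oxidative phosphorylation differed between the species at 12 h (adjusted p = 0.0011) and 72 h (0.00394), as did the cell cycle list at 12 h (0.0084) and 72 h (0.000424). With an estimated correlation none passed, both lists having an adjusted p = 0.233 at 12 h and 0.259 at 72 h.

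In S. oramin the cell cycle and oxidative phosphorylation lists were higher at 72 h than at 0 h with the preset correlation (adjusted p = 0.303 and 0.454 with an estimated correlation). The tables argue against the 0 h library with the most erythrocyte and muscle transcripts, replicate 1, as their source: without it the list medians were 1.1 for the cell cycle (0.95 with all libraries, 0.91 without replicate 2) and 1.0 for oxidative phosphorylation (1.12 and 1.27). For the cell cycle list they also argue against a shift of all genes, since its median was 0.89 after quantile normalization. That bound was set for the cell cycle list alone. After quantile normalization the oxidative phosphorylation list kept its call with the preset correlation. Whether the parasite or time and handling lies behind the pattern stays open. For this, 0 libraries of fish kept as long without the parasite were analysed here. A change in the cell make-up of the samples stays open too and was not tested for these lists. From 0 h to 72 h the erythrocyte score went from 0.89 ± 0.74 to −0.58 ± 0.17 and the muscle score from 0.43 ± 0.3 to −0.29 ± 0.02 (SD, n = 2 each).

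Immediate early and handling stress genes were lower at 72 h than at 0 h in S. oramin with the preset correlation (adjusted p = 0.319 with an estimated correlation), as were muscle and erythrocyte markers (both 0.443). Handling at 0 h that acts on both species alike is argued against by T. blochii, whose median at 72 h was 0.02 against −0.89 in S. oramin (joint spread of the scores of both species 0.41). The bound of that test lay between these medians, and T. blochii cleared it by little more than the joint spread. That spread at first held only the T. blochii scores at 0 h and was redefined later. Less muscle or blood in the later samples may contribute, since at 12 h the immediate early median was −0.13 beside −0.47 for muscle and −0.81 for erythrocytes, which passed the bound of −0.1 only narrowly, a bound set with the values known. Within 0 h the scores went the other way. Replicate 1 had the higher erythrocyte and muscle scores (1.42 and 0.64, against 0.37 and 0.22) but the lower immediate early score (0.09 against 0.53). The erythrocyte score also ran opposite to the immediate early score within 12 h, but with it within 72 h, so these few libraries do not decide. As the whole cause, in an assumed proportion, muscle and blood would have given −0.59 at 12 h against the −0.13 observed, a gap within the joint spread of the scores (0.86), so that stays open too. A handling difference in S. oramin alone stays open and was not tested.

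In T. blochii the ribosomal protein and oxidative phosphorylation lists were lower at 12 h than at 0 h with the preset correlation (both adjusted p = 0.899 with an estimated correlation). A single library may account for the latter, since its median was −0.002 without 12 h replicate 1, against −0.16 with all libraries and −0.17 or lower without another 12 h library. The ribosomal scores at 12 h and 0 h differed by 1.3 pooled SDs, within the bound of 2 set for chance spread between libraries of highly correlated genes, so that explanation also stays open. No biological explanation was tested for this pattern.

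The 6 libraries of each T. blochii comparison can be split in 10 ways, too few for a share under 0.05. For 12 h against 0 h the real split called 0 genes and the highest other 1. At an unadjusted p under 0.05 the real split had 213 genes, and the highest other, a split that called 0, had 1024. For 72 h against 0 h the calls were 0 and 2, with 704 and 811 genes at an unadjusted p under 0.05, and for 72 h against 12 h they were 0 and 1, with 937 and 571. Splits that mix the times thus ran from 66 to 1024 genes, where 380 would be expected. No splits were run for S. oramin or for the difference between the species. Their excess over the expected number was therefore not held against such a spread.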

How the results depend on the processing

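Size factors, the 2-group fits, the fold threshold, summed names, the replicate block and the leaving out of libraries were planned, and the pseudocount, mean filter, quantile, weight, variance prior, identical identifier and 0-value settings were chosen after seeing the data. Count-model tools and their normalizations and filters were not run because the values are not counts, and the count filter has no counterpart here. Depth is unknown, so its limit on low genes cannot be stated. The cause of each change below was not tested, except that leaving out a library or fitting 2 groups leaves fewer samples, and that a lone library left in a group is assumed to vary like the other groups.

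S. oramin 12 h against 0 h called 1 gene higher, and 0 with only the 2 groups or a replicate block; leaving out libraries gave 0 to 2. At 72 h 0 genes were lower, and leaving out libraries gave 0 to 11. For 72 h against 12 h 0 were higher and 1 lower, and array weights gave 16 and 21, 2 groups and the replicate block each 0 lower, and leaving out libraries 0 to 11 lower. In T. blochii at 72 h, 0 were called, and 10 higher and 1 lower with 2 groups, 247 and 137 with array weights, and 0 to 4 higher and 0 to 1 lower with libraries left out. For 72 h against 12 h array weights gave 9 higher, and left-out libraries 0 to 6 higher and 0 to 3 lower, against 0 and 0. Of the matched genes at 12 h, 0 differences were above 0 and 1 below, and the replicate block, array weights and a mean of at least 5 gave 0 below, and left-out libraries 0 to 15 above and 0 to 9 below. At 72 h, 4 were above and 1 below, and summed names gave 29 and 11, size factors within species 2 and 0, the replicate block 0 and 0, quantile normalization and a mean of at least 5 each 0 below, and left-out libraries 0 to 43 above and 0 to 19 below.

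Lists called were 14, 13 and 16 in S. oramin, 5, 7 and 11 in T. blochii, and 2 and 2 between species. With an estimated correlation each of these 8 counts was 0, and fry gave 1, 3, 0, 0, 0 and 0 within species and 0 and 3 between them. Leaving out libraries gave 12 to 19, 10 to 17, 15 to 17, 4 to 13, 7 to 12, 8 to 12, 1 to 3 and 1 to 3. KEGG pathways went from 2, 2 and 1 to 0, 0 and 0 with an estimated correlation.

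Signs reversed as follows. Without S. oramin 0 h replicate 1, L-amino-acid oxidase Sig_T020365 had −0.02 at 12 h and −0.48 at 72 h, and Sig_T020370 had −0.55 and −0.52, the highest values with another library left out being 3.89, 3.43, 3.58 and 3.61. For 72 h against 12 h Sig_T020370, at 0.03, had −0.18 with size factors, −0.03 with the replicate block, −0.1 after quantile normalization, −0.34 with array weights, −0.35, −0.03 and −0.01 without 12 h replicates 1 and 3 and 72 h replicate 2, and up to 0.46 without another library. In T. blochii at 12 h newGene_3759 had −0.01 and −0.34 without 0 h replicate 3 and 12 h replicate 1 (up to 0.96 without another), newGene_3760 had −0.18, −0.37 and −0.03 without those and 12 h replicate 3 (up to 0.78), and newGene_3758 for 72 h against 12 h had −0.04 without 12 h replicate 2 (up to 1.1). Lists that reversed had adjusted p of 0.352 for antimicrobial effectors and 0.686 for endothelium (S. oramin 12 h, without 0 h replicate 1), 0.519 and, after quantile normalization, 0.305 for ribosomal proteins (S. oramin 72 h), and 0.861 for oxidative phosphorylation (T. blochii 12 h, without 12 h replicate 1). The lowest adjusted p of these lists with a library left out were 7.24e-05, 4.98e-05, 8.87e-08 and 6.78e-09.

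Replicate numbers name different fish, and the values do not settle whether same-numbered libraries share anything else. Of same-number pairs, 3 of 6 in S. oramin and 3 of 9 in T. blochii had a correlation of deviations over 0.1 (0.005 to 0.213, and −0.239 to 0.377). With 2 libraries in a group the deviations mirror each other, so the S. oramin pairs are not independent. Of the libraries, 5 of 7 and 5 of 9 correlated best with their own number. The replicate block ended the calls of the 6 genes that differed between the species (adjusted p = 0.0803 for acetylserotonin O-methyltransferase-like and 0.0537 to 0.0589 for the others) and both eosinophil peroxidase-like calls (adjusted p = 0.0557 and 0.0549, over ranges of 0.0101 to 0.26 and 0.00293 to 0.159). It also ended the list calls of antimicrobial effectors (0.246) and endothelium (0.0641) at 12 h in S. oramin, and of chemokines (0.0549) and cholesterol synthesis (0.0588) for 72 h against 12 h in T. blochii. Over single genes and lists, 1095 alternatives kept the direction and side of the threshold, 260 lost the call, 2 gained one and 22 changed sign. Of the counts adjusted over a list alone with a library left out, run after seeing the data, 491 stayed within 1.5 times the reported count and 237 did not. Of the other counts of genes, lists and pathways, 297 alternatives stayed within 1.5 times the reported count and 82 did not.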

Other observations

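The list tests of this part were planned, and the single genes named in it were chosen after their values were seen. In S. oramin B cell genes had a median log2 fold change of −0.23 at 12 h (adjusted p = 0.645) and 0.44 at 72 h (adjusted p = 0.473), with 36 of 52 genes above 0 at 72 h, and in T. blochii of 0.20 (0.704) and 0.65 (0.0819), none past the test. From 12 h to 72 h in T. blochii a B-cell linker-like gene rose by a log2 fold change of 1.00 (list-alone adjusted p = 0.0284). Fatty acid metabolism had 0.05 (0.325) and 0.32 (0.395) in S. oramin and 0.03 (0.704) and −0.05 (0.364) in T. blochii. Arginine, tryptophan and polyamine metabolism had 0.09 (0.371) and 0.28 (0.433) in S. oramin and −0.19 (0.507) and −0.23 (0.252) in T. blochii.

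Acute phase proteins were tested in S. oramin, with 0.59 at 12 h (adjusted p = 0.0968) and 0.20 at 72 h (0.433), and in T. blochii too few genes were listed for a test. There alpha-2-macroglobulin-like, a protease inhibitor of plasma, had 1.97 ± 0.637, 1.35 ± 0.123 and 2.09 ± 0.617 at 0, 12 and 72 h (SD, n = 3 each). The skeletal muscle list was likewise too short in T. blochii, where slow troponin T, of the contractile fibre, had 21.3 ± 17.6, 9.15 ± 5.6 and 33.2 ± 45.2, and myosin regulatory light chain 2 had 9.65 ± 1.22, 11 ± 4.45 and 18.6 ± 17. Of the 11 eosinophil peroxidase-like copies of S. oramin 2 passed from 0 h to 72 h adjusted over the list alone, Sig_T007056 rising by a log2 fold change of 2.48 (list-alone adjusted p = 0.00948) and Sig_T007054 by 4.65 (0.0356). The other copies had log2 fold changes between −1.33 (Sig_T007053) and 0.71 (Sig_T007055), with −1.16 for Sig_T007049 and −0.65 for Sig_T007051.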
